A study of Mus musculus with 9 samples.

How the data were processed

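RNA from MIN6 cells, a mouse insulinoma line used as a model of pancreatic beta cells, was sequenced after 24 h in medium with 0.1, 1 or 20 times the standard arginine concentration. Each of the 3 media had 3 libraries, 9 in all. Groups and replicate numbers were taken from the labels. The labels do not state whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

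The deposited values are FPKM per gene, 1 column per library, with the gene length used for each gene, per the file headers. Libraries were made with a directional kit from total RNA, per the labels' protocols. The tools listed are CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here. The same notes name the build mm9, but of the 54409 gene IDs shared with GENCODE M21, 98.33% carry its GRCm38 start and end in the file, so coordinates are given here as GRCm38. The table holds 54876 genes. Of these, 344 have no symbol, and 100 symbols belong to more than 1 ID. The table had 0 unused columns of per-sample values.

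FPKM multiplied by gene length moved in whole steps in 100% of values, to within 0.01 reads, so each library's reads in genes were rebuilt from the table. They came to 21550637 to 26300872 per library, and a gene's precision follows its own reads among these. The library size behind each FPKM was 0.9621 to 1.0767 times these reads and followed median-of-ratios factors computed here, so a scale factor between libraries was already in the values the authors deposited. FPKM is not a count, so no count model was used. The rebuilt reads served for depth, scale factors, shares of reads, the reads behind single genes, the comparison of replicates, thinning and the fit with voom weights.

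Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 12300, of which 10771 were protein-coding. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. A single fit over all 9 libraries had group as its only term, with 6 residual degrees of freedom and a prior variance that followed mean expression. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested in each contrast, with a threshold of 0.05 and no fold threshold. The contrast of high with low arginine is also the test of the difference between both responses, since each is taken against the same standard libraries.

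Gene lists, 33 in number, were written from textbook knowledge. Those with at least 3 tested members, 31 lists, were tested with camera at a preset correlation of 0.01 and adjusted over the 93 list tests together. Calls were repeated with an estimated correlation and with fry, which called 24, 3 and 24 lists in low against standard, high against standard and high against low arginine. A list's median, mean and camera direction differed in sign in 11 of the 93 tests, of which 0 were called. Genes named in the text followed a rule. Per contrast it took the 10 largest rises and 10 largest falls (5 and 5 for high against low arginine) among called genes with a full symbol, a mean FPKM of at least 5 in the higher group and no overlap between groups. It added up to 4 called members per list with the smallest p and a fixed set of insulin, arginine and stress genes reported whatever their result. Some genes that the rule names are not reported here. The tests of genes, of the 33 lists and of the overlap, the naming rule and the alternatives were chosen before the data were examined, apart from 2 alternatives, thinned reads and removal of the trend on GC content and gene length. Those 2, and the tests and RNA lists used to weigh explanations in the other observations, were chosen after seeing the data.

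The procedure was tested on simulated data. For low against standard arginine, with 11991 genes run, 38%, 88%, 94% and 98% of changed genes were recovered at folds of 1.25, 1.5, 2 and 4, and 4.59% of calls were false. For high against standard arginine, with 11978 genes run, the shares were 48%, 90%, 96% and 98%, and 4.41% of calls were false. Both runs used the standard arginine means, the same spread and the same changed genes, so they differ mainly by random draw. They gave 196 and 204 calls, against 7646 and 38 in the real contrasts, so these shares need not hold there. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 2.785 to 14.9, so none was treated as a duplicate. Alternatives covered the pseudocount, the filter, scaling, the libraries in the fit, the variance model, library weights, a replicate block, a 2-fold threshold, voom weights and leaving out each library. For the overlap of both responses, 100 draws with no effect were simulated against shared standard libraries.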

Results

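MIN6 beta cells were cultured for 24 h in low, standard or high arginine medium, at 0.1, 1 or 20 times the standard concentration, and their transcriptomes were sequenced. Each group had 3 libraries. Reads in genes numbered 24835801, 26300872 and 26152673 in the low, 24452040, 21550637 and 22129427 in the standard and 24001161, 23747593 and 24163731 in the high arginine libraries. Ins2, an insulin gene, took 7.25 ± 0.0321% of reads in low, 6.55 ± 0.291% in standard and 6.14 ± 0.0252% in high arginine (SD, n = 3 each). The first principal component held 76.8% of the variance and placed the 3 low arginine libraries at -39.7 to -36.4 and the other 6 at 16.8 to 20.3. Stromal markers were scarce, while several markers of other islet cells were not. None of the 12 fibroblast and stromal markers was tested, and Col1a1, the highest, had a mean of 0.0612 FPKM. Of the delta and PP cell list 2 markers were tested, too few for a list test; Sst, which encodes somatostatin, was abundant at 5790 ± 391 FPKM in standard arginine. Of the alpha cell markers, Ttr had a mean of 690 FPKM over the 9 libraries and Gcg of 23 FPKM.

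The first comparison asked how a deficient arginine supply changed the transcriptome. In low arginine, genes of lipid synthesis, glycolysis and protein folding in the endoplasmic reticulum (ER) fell, while stress-response targets of the transcription factor ATF4 rose. Scd1, a fatty acid desaturase (chromosome 19, 44394451 to 44407709), dropped from 90.9 ± 7.05 to 2.73 ± 0.269 FPKM (SD, n = 3 each). Angptl8, a secreted regulator of lipid metabolism (chromosome 9, 21835510 to 21837347), rose from 15.3 ± 2.16 to 258 ± 24.5 FPKM. Of the 12300 genes tested, 3723 rose and 3923 fell in limma at a Benjamini-Hochberg adjusted p under 0.05. Together these were 62.2% of those tested, the share to set beside counts of called list members in this contrast. Of the called genes, 236 rose and 403 fell at least 2-fold. In TPM, 4843 rose and 3018 fell, where the median of all genes was 0.115 on the log2 scale against 0.001; the higher share of calls was 61.6% there against 48.7%.

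All 24 tested genes of cholesterol synthesis and uptake fell, by a median log2 change of -2.36, and the same 24 were called when adjusted over the list alone. The log2 change was -3.47 (SE 0.07) for Hmgcs1, an enzyme of the mevalonate pathway, and -3.12 (SE 0.06) for Insig1, a regulator of that pathway. Nsdhl, Mvd and Cyp51, enzymes of cholesterol synthesis, were also among the 10 largest falls, at -3.01, -2.81 and -2.78. Cyp51 is uncertain, since it overlaps Akap9 on the other strand and the strand setting of the counting is not known. The camera call for the list had an adjusted p of 3.12e-17, and an adjusted p = 0.4 with an estimated correlation. Of 15 fatty acid synthesis genes, 13 fell and 1 rose, as they did adjusted over the list alone. The log2 change was -4.62 (SE 0.08) for Scd1, -3.38 (SE 0.07) for Scd2, -2.34 (SE 0.09) for Fasn, the fatty acid synthase, and -1.66 (SE 0.06) for Srebf1. That list had a camera adjusted p of 2.67e-06, and an adjusted p = 0.4 with an estimated correlation.

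Of 18 glycolysis genes, 14 fell and 2 rose, with a median log2 change of -1.65 and the same counts adjusted over the list alone. Ldha, lactate dehydrogenase A, fell from 552 ± 74.0 to 82.7 ± 4.94 FPKM, a log2 change of -2.72 (SE 0.10), and those of Pfkl, Gpi1 and Pgk1 were -2.35, -2.06 and -1.81. Slc16a3, a lactate transporter, fell by 3.41 (SE 0.14). The camera adjusted p of the list was 4.74e-06, and an adjusted p = 0.612 with an estimated correlation. Gapdh (-0.55, SE 1.06, not called) and both Aldoa entries (-1.58, SE 0.12, and 0.66, SE 0.08) are uncertain, because near-identical copies or a neighbouring entry of the same gene can share their reads. Of 14 hypoxia-inducible genes 11 fell, with Bnip3 at -2.71 and Fam162a at -2.40, while Vegfa was among the 3 that rose, by 1.24 (SE 0.06); the counts were the same adjusted over the list alone. Camera gave an adjusted p of 0.00438, and an adjusted p = 0.612 with an estimated correlation.

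Of 36 ATF4 amino acid response targets, 32 rose and 1 fell, also when adjusted over the list alone, with a median log2 change of 0.84. Atf3 rose by 2.85 (SE 0.08), Ddit3, which encodes CHOP, by 2.17 (SE 0.07), Trib3 by 1.91 (SE 0.09), Cebpg by 1.69 (SE 0.06), Nupr1 by 1.61 (SE 0.07) and Chac1, a glutathione-degrading enzyme, by 1.19 (SE 0.08). Atf4 itself (log2 change -0.13, SE 0.06, adjusted p 0.078) and Asns, asparagine synthetase (-0.07, SE 0.06, adjusted p 0.35), did not pass the test, but under quantile normalization both were called higher, at 0.15 and 0.13. The camera adjusted p was 3.38e-11, and an adjusted p = 0.4 with an estimated correlation. Of 30 ER folding genes 23 fell and 2 rose, with the same counts adjusted over the list alone. Pdia4 was at -1.35 (SE 0.06), Manf at -1.33 (SE 0.06), Edem1 at -1.23 (SE 0.05) and Pdia6 at -1.19 (SE 0.06). Hspa5, the ER chaperone BiP, fell by 0.25 (SE 0.07, adjusted p 0.011), but under quantile normalization it was called higher, at 0.22. The camera adjusted p of the list was 2.14e-06, and an adjusted p = 0.4 with an estimated correlation.

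Beta cell genes moved both ways. Of 29 tested, 10 rose and 12 fell, as they did adjusted over the list alone, and the list had no camera call (adjusted p 0.992, and adjusted p = 0.994 with an estimated correlation; median 0.006 and camera direction up, but mean -0.039). Nkx6-1 and Pdx1, transcription factors of beta cell identity, rose by 1.5 (SE 0.06) and 1.31 (SE 0.07). Mafa rose by 0.33 (SE 0.07). Pcsk1, a proinsulin-processing convertase, was at -1.8 (SE 0.08), and Trpm5, an ion channel, at -1.16 (SE 0.06). Ins1 fell from 1542 ± 133 to 1065 ± 43.1 FPKM. Ins2 did not pass in limma, at 50610 ± 3623 FPKM in standard and 52070 ± 596 FPKM in low arginine (log2 change 0.04, SE 0.06, adjusted p 0.57). Across the alternatives run, the Ins2 change ran from -0.01 to 0.17. Its share of reads was 7.25% in low and 6.55% in standard arginine, so this result rests on how libraries are scaled. Among exocytosis genes 5 of 25 rose and 11 fell, the same adjusted over the list alone, with Kcnj11 at 0.95 (SE 0.08) and Ptprn2 at -1.27 (SE 0.07); camera made no call (adjusted p 0.433, and adjusted p = 0.916 with an estimated correlation).

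Of 13 arginine transport and metabolism genes 5 rose and 7 fell, also adjusted over the list alone. Slc7a1, the main cationic amino acid transporter, rose by 0.95 (SE 0.07). Prmt1, an arginine methyltransferase, also rose (adjusted p 1.1e-06). Asl and Gamt were at -1.01 (SE 0.06) and -1.20 (SE 0.12), and Ass1 at -0.32 (SE 0.10); Slc7a2 rose by 0.19 (SE 0.07). Odc1, the first enzyme of polyamine synthesis, rose by 0.67 (SE 0.08). Arg2 was below the filter, at 0.631 ± 0.0827 FPKM in low and 0.582 ± 0.232 FPKM in standard arginine. The list had no camera call (adjusted p 0.929, and adjusted p = 0.974 with an estimated correlation). Camera called 18 of 31 lists in this contrast, 9 in high against standard and 16 in high against low arginine; with an estimated correlation 0 of these calls held, and the smallest adjusted p was 0.4 in each contrast.

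**Figure D1:**
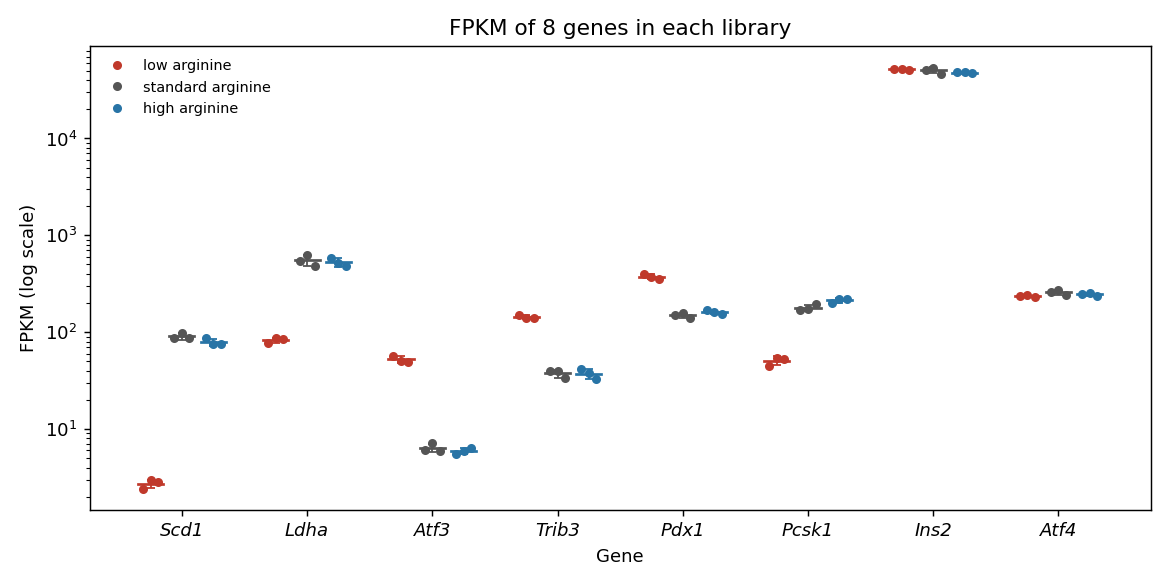
FPKM on a log axis for 8 genes, with 1 point per library, a bar at the mean and error bars of 1 SD (n = 3 per group). Scd1, Ldha and Pcsk1 lie lower and Atf3, Trib3 and Pdx1 higher in the low arginine libraries. Ins2 and Atf4 did not pass the test in the main fit.

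The second comparison asked what an excess of arginine changed. Called changes were few and small in the main fit, and their number depended on the setting. Chst1, a sulfotransferase (chromosome 2, 92599707 to 92615250), rose from 8.96 ± 1.12 to 14.6 ± 0.616 FPKM, a log2 change of 0.65 (SE 0.08, adjusted p 0.016). Mat2a, which makes S-adenosylmethionine, rose by 0.51 (SE 0.07), Scgn by 0.57 (SE 0.09), and Slc30a8, the zinc transporter of insulin granules, by 0.40 (SE 0.05). Among the falls, Cdkn2b, a cell cycle inhibitor, was at -0.57 (SE 0.07), Trappc6a at -0.57 (SE 0.09), the cold-inducible genes Rbm3 and Cirbp at -0.45 (SE 0.07) and -0.42 (SE 0.06), and Snap25, a protein of vesicle fusion, at -0.40 (SE 0.06). Mat2a and Fen1 are uncertain, since they overlap Particl and Tmem258 on the other strand.

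In all, 17 genes rose and 21 fell of 12300 (limma, Benjamini-Hochberg), and 1762 had an unadjusted p under 0.05. That share is above the 0.05 that genes with no effect would give on average. Changes too small to call may thus be present, but the excess was not tested, and genes are not independent. With the trend on GC content and gene length removed 161 rose and 88 fell, a higher share of 64.7% against 44.7%. The other named rises were Mylpf, Fen1, Ddit4l, E2f2, Lpcat1 and Zfp185, at 0.37 to 0.44, and the other named falls Scrn2, S100a11, Nipsnap2, Eno3 and Cyb5r1, at -0.46 to -0.39. Mir7682, singled out after its values were seen, had the largest called change, 1.92, but rests on a mean of 4 reads in high arginine. These calls depended on single libraries. Without standard replicate 2 or high replicate 3 limma called 0 genes (1209 and 1197 at an unadjusted p under 0.05), and without high replicate 2 it called 1. Without standard replicate 1 or high replicate 1 it called 10 and 20, while without standard replicate 3 it called 61. Without low replicate 3, 2 or 1 it called 13, 20 and 42. Low arginine libraries do not enter this fold change and act only through the shared estimate of the spread. A fit of only the 6 libraries compared called 0 (1669 at an unadjusted p under 0.05), voom weights 74 and array weights 1323.

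Of 41 DNA replication and S phase genes 40 had a log2 change above 0, with a median of 0.16; Fen1 passed the test over all genes (0.42, SE 0.06), and 18 passed when adjusted over the list alone. Camera gave an adjusted p of 5.67e-13, and an adjusted p = 0.4 with an estimated correlation. Of the 24 cholesterol genes 0 passed in limma, over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05, with a median of -0.13 (camera adjusted p 7.68e-06, and adjusted p = 0.53 with an estimated correlation). The 13 mitochondrially encoded genes were all above 0, with a median of 0.24, and limma called 0 by either adjustment, with 7 at an unadjusted p under 0.05 (camera adjusted p 0.000113, and adjusted p = 0.443 with an estimated correlation). Of the ATF4 targets 0 of 36 passed in limma by either adjustment and 7 had an unadjusted p under 0.05, with a median of -0.04 (camera adjusted p 0.326, and adjusted p = 0.916 with an estimated correlation). Of the 29 beta cell genes Slc30a8 alone passed over all genes, and 3 passed adjusted over the list alone (camera adjusted p 0.00612, and adjusted p = 0.443 with an estimated correlation). Ins1, Ins2, Pdx1, Mafa, Slc7a1, Asl, Odc1, Ddit3, Trib3, Chac1 and Hspa5 did not pass, with log2 changes of -0.15 to 0.22.

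**Figure D2:**
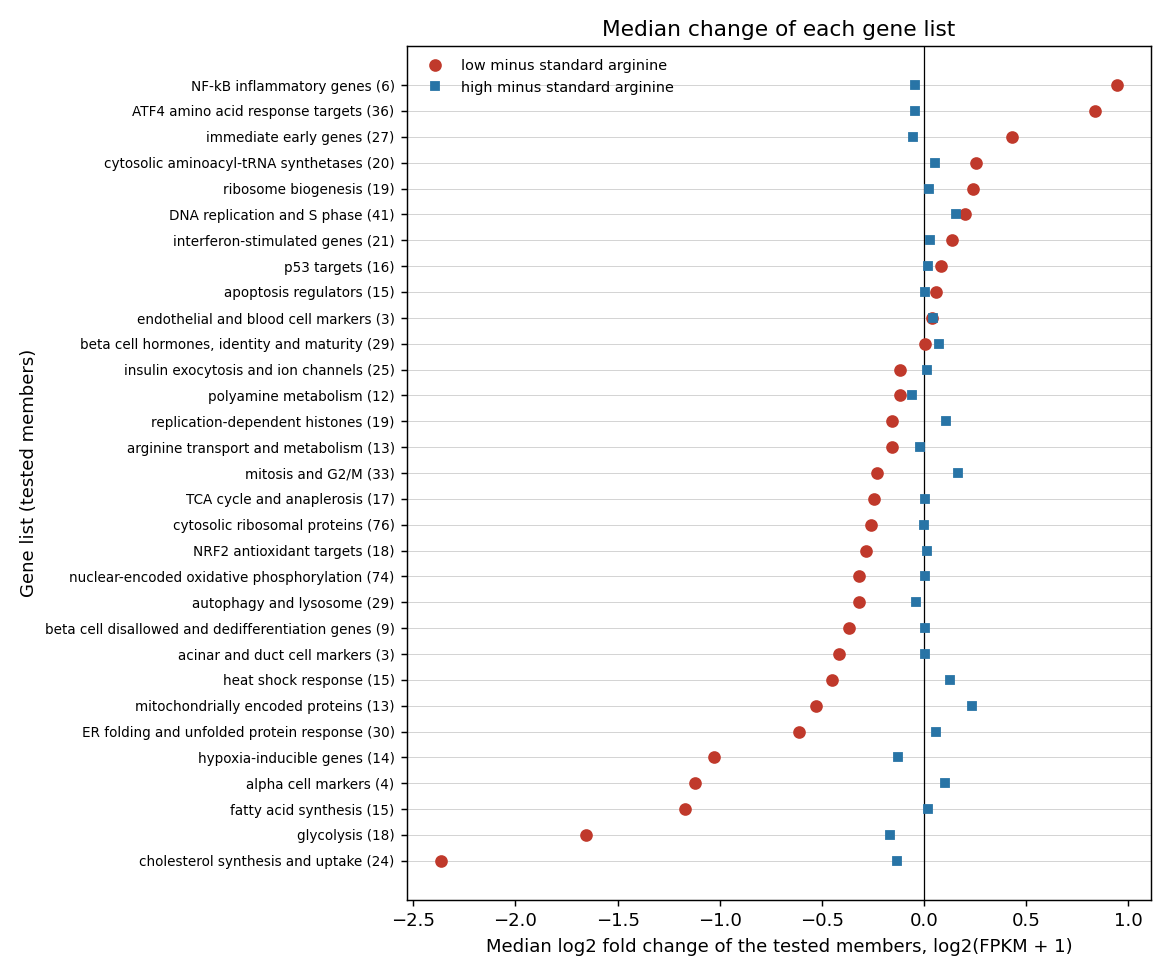
Median log2 fold change of the tested members of each of 31 gene lists, as circles for low minus standard and squares for high minus standard arginine, with the number of members in parentheses. Low arginine medians ran from -2.36 for cholesterol synthesis to 0.94 for NF-kB genes, and high arginine medians from -0.17 to 0.24.

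The third comparison set high against low arginine, which also tests whether both responses differed. Scd1, Hmgcs1, Scd2 and Slc16a3 were higher in high arginine by 4.43, 3.33, 3.26 and 3.13, and Angptl8, Cxcl10, Atf3, Ccl20 and Mir7k lower, at -4, -3, -2.94, -2.74 and -2.70; the last, a microRNA gene, had an SE of 0.41. In limma 3967 genes were higher and 3594 lower at a Benjamini-Hochberg adjusted p under 0.05, together 61.5% of those tested. In TPM these were 3094 and 4735, so that the higher share of calls was 39.5% there and 52.5% here. The 24 cholesterol genes were all higher, also adjusted over the list alone (camera adjusted p 1.27e-16, and adjusted p = 0.4 with an estimated correlation), and of 36 ATF4 targets 30 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p 1.99e-11, and adjusted p = 0.4 with an estimated correlation).

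Both responses shared 30 called genes. Fen1, Scgn, Chst1, Lpcat1, Mylpf and Zfp185 fell in low and rose in high arginine, at -0.55, -0.53, -0.23, -0.80, -0.99 and -0.55 in low arginine. Snap25, Trappc6a, S100a11 and Eno3 fell in both. In total 14 genes moved the same way and 16 opposite ways, where independent lists would share 11.8 each way and simulated libraries with no effect 0.02 and 0; the simulated values leave out the real effects, so they lie near 0 by construction and do not bear on shared calls. Without standard replicate 2, high replicate 2 or high replicate 3 these became 0 and 0; without low replicate 2, 7 and 7; without low replicate 3 or standard replicate 1, 5 and 3; without high replicate 1, 9 and 5; and without standard replicate 3, 31 moved the same way. Across genes, which are not independent replicates, fold changes had a correlation of 0.155 (0.501 simulated with no effect). The simulated correlation also leaves out the real effects, so 0.155 and 0.501 cannot be compared. The covariance of the fold changes was 0.0121 (0.0053 simulated), a difference of 0.0068. Each response used the same 3 standard libraries, too few to divide. Noise in these shared controls moves both responses the same way. Part of any excess in the same direction may come from it, but not an excess in opposite directions. The simulated covariance already includes such noise at the fitted spread.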

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

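Of the named genes under the alternatives run, 6961 values kept their call, 351 lost and 15 gained it, and 5 changed sign with a call in at least 1 setting. For the remaining list calls these were 2048, 67, 28 and 1. Values that changed sign without a call in either setting count among those that kept their call. Thinned reads and removal of the GC content and length trend were chosen only after the data were seen. Median-of-ratios scaling repeats a factor already in the values and moved nothing. Leaving out 1 library gave 3333 to 3712 rises and 3568 to 3933 falls in low against standard arginine. In high against standard arginine it gave 0 to 26 rises and 0 to 35 falls, and an overlap of 0 to 31 genes in the same and 0 to 19 in the opposite direction; in high against low arginine it gave 3601 to 4120 and 3234 to 3758. With a mean FPKM of at least 5, which tests fewer genes, 2328 rose in low arginine, 26 rose in high arginine and 2190 were lower in high than in low. A 2-fold threshold left 236 rises and 403 falls in low, 1 and 0 in high against standard, and 420 and 234 in high against low arginine, with 0 shared genes in either direction.

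The high against standard counts, 17 and 21, and the overlap, 14 same and 16 opposite, moved most. Given as rises, falls, same and opposite, they were 4, 2, 5 and 0 without a filter on low values, 0, 0, 0 and 0 with only the 2 groups compared, 713, 610, 686 and 292 with array weights, and 40, 34, 28 and 28 with voom weights. With the GC content and length trend removed they were 161, 88, 106 and 90. With thinned reads 11 rose, 13 fell and 8 were shared in the same direction. The cause was not tested. With a replicate block they were 46, 42, 38 and 30. The replicate numbers were not taken to pair the samples, since not every same-number pair had a correlation of deviations over 0.1: 6 of 9 did, and the values ran from -0.04 to 0.24. All 3 pairs of low with high arginine did (0.24, 0.15 and 0.22), and a library correlated best with its own number in 14 of 18 comparisons, a hint of pairing from the data and not the design. In high against low arginine the block gave 4194 higher and 3866 lower genes.

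With an estimated correlation, camera's adjusted p was 0.4 for the ATF4, ER folding, cholesterol and fatty acid lists and 0.612 for glycolysis in low arginine, and 0.4 for DNA replication and 0.53 for cholesterol in high arginine. Across all alternatives these p ranged from 1.74e-16, 1.23e-11, 3.53e-28, 9.04e-11 and 5.56e-09 for the ATF4, ER folding, cholesterol, fatty acid and glycolysis lists up to those values. With fry the cholesterol list in high arginine had an adjusted p of 0.104. Under quantile normalization the low arginine change became 0.22 for Hspa5, 0.15 for Atf4 and 0.13 for Asns, all called higher, and in high against low arginine -0.11 for Hspa5 and -0.2 for Atf4; the ribosomal protein list in that contrast reversed, at an adjusted p of 0.863. The cause was not tested. At the smallest fold simulated, 38% of changes were recovered in the low and 48% in the high arginine run, which differ mainly by random draw. Small changes can therefore be missed, but these shares need not be those of the real contrasts. Depth and the spread between replicates were not separated in this.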

Other observations

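The tests of scaling, thinned reads and GC content and length below, and the host RNA, decay factor and nuclear RNA lists, were chosen only after results had been seen. Low arginine also moved groups of genes not described above. Of 27 immediate early genes 16 rose and 6 fell, with Dusp6 at 1.68 (SE 0.09), Jun at 1.48 (SE 0.08) and Klf10 at 1.44 (SE 0.07), and of 6 NF-kB genes 4 rose and 1 fell, among them Nfkbia at 1.49 (SE 0.08) and Relb at 1.08 (SE 0.07); adjusted over the list alone the counts were 16 and 6, and 5 and 1. Camera gave them adjusted p of 0.0044 and 0.0166, and an adjusted p = 0.426 and 0.499 with an estimated correlation. Of 19 ribosome biogenesis genes 13 rose and 2 fell (14 and 2 adjusted over the list alone), with Nop58 at 1.62 (SE 0.10), Nop56 at 1.58 (SE 0.10) and Myc at 1.49 (SE 0.08) (camera adjusted p 0.00362, and adjusted p = 0.4 with an estimated correlation). Of 15 heat shock genes 10 fell and 2 rose, the same adjusted over the list alone, led by Hspa8 at -1.68 (SE 0.06), and of 74 nuclear-encoded oxidative phosphorylation genes 50 fell and 8 rose (51 and 9 adjusted over the list alone), with Cox6b1 at -1.39 (SE 0.07); camera gave adjusted p of 0.0154 and 1.19e-05, and adjusted p = 0.612 for both with an estimated correlation. Of 13 mitochondrially encoded genes 11 fell and 0 rose (12 fell adjusted over the list alone), with mt-Nd2 at -1.08 (SE 0.07) and a median of -0.53 (camera adjusted p 0.00127, and adjusted p = 0.53 with an estimated correlation). Of 41 DNA replication genes 21 rose and 6 fell, with Mcm4 at 1.05 (SE 0.06), while of 33 mitosis genes 17 fell and 4 rose, with Aurkb at -1.31 (SE 0.08) (camera adjusted p 0.00738 and 0.0349, and adjusted p = 0.702 and 0.764 with an estimated correlation; the same counts adjusted over the list alone). Ribosomal protein genes, 41 of 76 lower and 8 higher, share reads with many pseudogenes and are uncertain; under quantile normalization 22 were lower and 26 higher.

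Among hormones and markers of other islet cells, 3 of the 4 tested alpha cell markers fell in low arginine, Slc38a5 at -2.48 (SE 0.15), Ttr at -1.62 (SE 0.10) and Gcg at -0.62 (SE 0.10), and 1, Gc, rose by 0.37 (SE 0.09), the same adjusted over the list alone. Sst, singled out after its values were seen, rose from 5790 ± 391 to 9758 ± 1342 FPKM. The alpha cell list had no camera call (adjusted p 0.122, and adjusted p = 0.612 with an estimated correlation). An unannotated locus on chromosome 13 (87668216 to 87672863), also singled out after its values were seen, fell by 3.91 (SE 0.08); the nearest protein-coding gene, Edil3, lies 1148609 bp away.

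Of the 10 largest named rises 3 were noncoding hosts of small nucleolar RNAs, Snhg12, Snhg1 and Zfas1, at 2.73, 2.48 and 2.43, where Zfas1 is uncertain, since it overlaps Znfx1 on the other strand. Leaving out these and Gas5, which had been seen first, 5 of 8 other hosts rose and 2 fell, with a median of 0.78, and enrichment of the hosts was not tested. Such hosts are known targets of nonsense-mediated decay, and less of that decay is a candidate explanation. Of 7 decay factor genes that are themselves targets 6 rose and 0 fell, with a median of 0.54 (exact sign test over the called genes, two-sided, p = 0.0313). That test treats genes as independent, although they come from the same libraries and can move together. Its p therefore measures no spread between samples. These factors can also rise for other reasons. More nuclear RNA in these libraries stays open, since only 3 nuclear long RNAs were tested, with a median of 0.04, of which Neat1 rose (permutation test against the hosts, exact, two-sided, p = 0.418). The arginine supply itself remains the designed difference.

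The falls of the lipid, ER folding and glycolysis lists and the rise of the ATF4 list were set against 3 technical explanations. With the trend on GC content and gene length removed, the 5 list medians kept their direction, the smallest being 0.709 in size. With reads thinned to the smallest library 7601 genes changed, against 7646, and the medians kept their sign. In TPM the smallest median was 0.508 in size, again with every sign kept. TPM moves all genes of a library nearly alike, and the median of all genes was only 0.115 there. That shift is smaller than any of the 5 medians, so this test could not decide on scaling. The values with the trend removed and with thinned reads argue against GC content and length, and against depth, as the whole cause. The contrast and the 5 lists were chosen before the data were examined, but the technical tests were not. Arginine supply is the designed difference, while scaling and technical causes not tested here stay open.

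In high against standard arginine 40 of 41 DNA replication genes had a log2 change above 0. Only 1 passed in limma over all genes (18 adjusted over the list alone). None passed in 6 of the 9 fits without 1 library, among them those without low replicate 2 or 3, which do not enter this fold change. Camera gave the list an adjusted p = 0.4 with an estimated correlation. The calls are therefore uncertain, and those of genes may rest on single libraries. Without standard replicate 3, which stood apart on the fourth principal component at -14.5, the list median was 0.18, against 0.16 with all libraries, and leaving out any other library gave 0.145 to 0.216. This argues against 1 library as the source of the median, not of the calls. The list's mean log2 level was 4.674 to 4.699 in the standard, 4.786 to 4.932 in the high and 4.87 to 4.975 in the low arginine libraries, with high below low in all 3 same-number pairs. High against low arginine had no camera call, with or without a replicate block (without it 11 higher, 13 lower, or 10 and 12 adjusted over the list alone, median -0.005, adjusted p 0.557, and adjusted p = 0.954 with an estimated correlation), so lower values shared by the standard libraries stay open beside a response to arginine, as hypotheses.

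Of the 10 ways to split the 6 libraries of a comparison into groups of 3, the real split gave 7308 changed genes for low against standard arginine and the highest other 0; 1 split gave as many. For high against low arginine the values were 7737 and 0, with 1 split giving as many. For high against standard arginine the real split gave 0 in limma, with 1669 genes at an unadjusted p under 0.05, and the highest other 2; all 10 splits then give as many by construction, so this count carries no information. The splits are too few for a share under 0.05.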
